A study of Mus musculus with 16 samples.

How the data were processed

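Gene expression was measured in the mouse mammary tumour line 4T1 and in its subline 4T1.2, each untreated or treated with TARC-PE38. The treated cultures carry the names 4T1-PE and 4T1.2-PE. Total RNA was copied into biotin-labelled cRNA and hybridised to Illumina MouseRef-8 v1.1 BeadChips, per the labels' protocols, which gave 1 colour per array. The 16 arrays came from 12 RNA samples, 3 in each of the 4 groups, because 4 samples (4T1 replicate 1, 4T1.2 replicates 2 and 3, and 4T1.2-PE replicate 3) were hybridised again.

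The authors deposited the mean bead intensity of each of 24620 probes on each array, on a linear scale with no normalization and no background subtraction, per the file headers. They were extracted with BeadStudio 3.1.7, per the file headers and the submitters' processing notes. Beside each intensity the deposited table gives a detection p-value, which compares the probe with the array's negative controls, per the file headers. The authors also deposited a z-score per probe and array. The authors made each score from the natural log of the intensity, minus the array's mean and divided by its standard deviation, over probes with a detection p under 0.02, per the labels. The scores were checked against the intensities. Each of the 16 columns of scores followed the natural log of its own array's intensities, and all 11590 probes with a score whose target is listed once were detected on at least 1 array. The median score per array lay between -0.353 and -0.229, and the scores served as an alternative.

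Intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc estimated the background from the detection p-values, added an offset of 16, normalized the arrays by quantiles and took log2. Values printed as log2 intensity are on that scale, on which the offset understates the change of dim probes. Repeat arrays of an RNA sample were averaged to 1 replicate. A probe was kept if its detection p was under 0.02 on every array of at least 3 of the 12 RNA samples, and the probe with the highest mean stood for a gene, which left 10094 probes and 8187 genes. In all, 8 control probes were left out, among them a probe for 18S ribosomal RNA that the file names Pigt. A further 3 probes with a value under 40 on some array were left out after the data were seen. Array intensities carry no counts, so the number of arrays and the signal over background set the precision.

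Probes were named through a table of RefSeq accessions and symbols of assembly GRCm38.p6, used for names only. The accession named 20514 probes, the symbol 1601 and a synonym 1696, the file's own symbol was kept for 577, and 232 had none. For 74 probes the accession and the file's symbol pointed to different current genes, and the accession was followed. No Alox5 probe was found under any of these names, so Alox5 was not analysed here. The files name no genome build, so no coordinates are given.

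One linear model with the 4 groups and no block was fitted per gene (lmFit, eBayes, 3.98 prior degrees of freedom). The contrasts were 4T1-PE against 4T1, 4T1.2-PE against 4T1.2, 4T1.2 against 4T1, 4T1.2-PE against 4T1-PE, and the difference between the treatment changes of the lines. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p for a gene is limma's. Where a probe was detected on no array of a group, the change is a bound: the bright group's mean is set against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own value, and is written "at least N-fold". Errors are the standard deviation of 3 RNA samples (SD) or the standard error of the fitted log2 change (SE). An exact permutation test of 3 against 3 samples cannot give a p under 0.1, and so was not used for single genes.

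The 19 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but 1. They cover eicosanoid synthesis, PPARalpha targets, chemokine receptors, chemokines and cytokines, epithelial and mesenchymal genes, matrix proteases and inhibitors, interferon response, class I antigen presentation, cell cycle, the diphthamide and exotoxin A pathway, unfolded protein and integrated stress response, NF-kappaB targets, hypoxia and glycolysis, cholesterol synthesis, NRF2 and glutathione, and leukocyte, fibroblast and endothelial markers. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. The estimated correlation and the fry rotation test were alternatives. The named genes are Ccr4, Alox5, Alox5ap, Lta4h, Ltc4s and Ppara. To these were added the 10 largest rises and 10 largest falls in each treatment contrast among called genes whose samples do not overlap. Comparisons between lines and the difference of changes took 5 and 5, the last without the overlap condition. Each list gave up to 4 members with the smallest adjusted p per treatment contrast, or the 2 with the largest change where none passed. Names without a standard symbol were passed over. Genes outside this rule are marked where they appear, and were chosen after their values were seen. Lists of macrophage, T cell, B cell, erythroid with megakaryocyte, and Y-linked markers were written after the leading genes had been seen and before they were tested.

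Replicates 1, 2 and 3 exist in each group, and the labels do not say what a number shares. Deviations from the group means were correlated between samples of different groups. The 18 pairs with equal numbers had r between 0.154 and 0.608, the 36 pairs with different numbers between -0.569 and 0.206, and 12 of 12 samples correlated best with a sample of their own number. The numbers therefore appear to pair the samples, a reading that comes from the data alone. The main fit, fixed beforehand, ignores this pairing, and all values come from it unless an alternative is named. A fit with the replicate number as a block was made beside it. Repeat arrays correlated with the first array of their sample at r of 0.986 to 0.995, above every other sample of their group (at most 0.981). One label calls 4T1 replicate 2 a technical replicate of replicate 1, against its title. Their r was 0.979, below that of the repeat arrays, and the title was followed, with both other readings as alternatives.

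Other alternatives were the z-scores, median scaling, no background correction, no detection filter, detection on all 16 arrays, all arrays with the RNA sample as a random block, first arrays only, the mean of a gene's probes, an intensity trend with robust settings, array weights, only the groups of a contrast, a 2-fold minimum, and each RNA sample left out in turn. After the data had been seen, a fit without 4T1 replicate 1 and with the replicate block was added. The files name no slides, so a slide term was not run. The procedure was tested on simulated data for 4T1-PE against 4T1 with 8777 genes. There it recovered 19 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, and 6 of 105 calls were false (5.71%). The simulated changes were placed only in probes detected on every 4T1 array, with 1 common spread and independent samples. These rates therefore do not cover genes silent in a group, an outlying sample or the likeness of samples with equal numbers. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.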

Results

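Transcript levels were measured in cultured 4T1 cells, a mouse mammary tumour line that metastasises spontaneously in BALB/c mice, and in its subline 4T1.2. Each line was examined untreated and after TARC-PE38, a fusion of the chemokine TARC with a truncated Pseudomonas exotoxin. The toxin part inactivates elongation factor 2 and so stops protein synthesis in cells that take it up. Per the labels, the treated cultures, named 4T1-PE and 4T1.2-PE, are no longer metastatic. Each of the 4 groups held 3 RNA samples, and 4 of the 12 samples had a repeat array, which made 16 arrays. The median intensity per array lay between 130.3 and 152.4, and between 7709 and 9584 probes (31.3% to 38.9%) were detected. No label says that the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Treated and untreated samples separated along the first principal component, which held 62.6% of the variance.

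Ccr4 encodes the receptor of TARC and was examined first. Its probe was detected on 0 of 16 arrays. The mean log2 intensity was 5.06 ± 0.16 in 4T1, 5.14 ± 0.07 in 4T1-PE, 4.99 ± 0.13 in 4T1.2 and 5.11 ± 0.08 in 4T1.2-PE (SD, n = 3), all at the background of the array. A Ccr4 transcript was thus not detectable with this probe, before or after treatment.

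The first comparison asked what TARC-PE38 left in the 4T1 culture. Transcripts of macrophages and other myeloid cells rose the most. Lyz2, which encodes lysozyme, went from a log2 intensity of 7.25 ± 3.51 to 14.32 ± 0.11 (SD, n = 3), a 134-fold rise (log2 change 7.07, SE 1.19, adjusted p = 0.00134). The lysosomal membrane protein gene Laptm5 rose 127-fold, and the glycoprotein gene Gpnmb rose 63.0-fold (adjusted p = 5.06e-05). Further leading rises were those of C1qb and C1qc of complement, the Fc receptor genes Fcer1g and Fcgr3, Ms4a6d and Cd68, with log2 changes of 5.50 to 5.91. C1qc was detected on no untreated array, and its rise is at least 26.8-fold. The largest falls were smaller. Cavin2, a caveolar coat gene, was 8.67-fold lower (log2 change -3.12, SE 0.52, adjusted p = 0.00118) and Edn1, which encodes endothelin 1, at least 4.54-fold lower (adjusted p = 0.0012). Prss12, Col8a1, Myo5c, Ccn2, Sertad4, Akap12, Chrnb1 and Tlcd4 fell with log2 changes between -2.65 and -2.29. In all, 857 genes rose and 808 fell among 8187 tested, of which 72 rose at least 16-fold. With the replicate number as a block 2424 genes changed, 1151 higher and 1273 lower, so that the falls outnumbered the rises. The values of treated and untreated samples did not overlap for 37.9% of genes, against 10% by chance.

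In 4T1 replicate 1, Lyz2, Laptm5, C1qb, Fcer1g, Fcgr3, Ms4a6d and Cd68 were detected without treatment, on both of its arrays and in neither other 4T1 sample. Lyz2 stood at a log2 intensity of 11.30 there, against 5.14 and 5.32 in 4T1 replicates 2 and 3, and Laptm5 at 11.91 against 4.75 and 4.93, while C1qc stood at 5.73, undetected, against 4.67 and 4.78. Without this sample, a choice made after seeing the data, 1361 genes changed (702 higher and 659 lower), and 1822 with the replicate number as a block. The rises of the 7 genes are then bounds, of at least 294-fold for Lyz2, 269-fold for Laptm5, 60.1-fold for Fcer1g, 42.8-fold for Ms4a6d, 41.5-fold for Fcgr3, 37.9-fold for Cd68 and 37.7-fold for C1qb. Cavin2 was 13.4-fold lower without that sample. Without 4T1 replicate 2 or 3, Lyz2 rose 64.4-fold and 68.4-fold, Laptm5 54.4-fold and 58.0-fold and Fcer1g 33.4-fold and 34.7-fold, and Edn1 was at least 6.82-fold and 2.99-fold lower. Without 4T1 replicate 3, Gpnmb rose 107-fold and Cavin2 was 5.65-fold lower. The call for C1qb was lost without 4T1 replicate 3 or without 4T1-PE replicate 1 (highest adjusted p = 0.0635). That for C1qc was lost without 4T1 replicate 2 or 3 or 4T1-PE replicate 1 or 2 (highest adjusted p = 0.114). C1qb was 37.5-fold higher without 4T1-PE replicate 1 and 129-fold without replicate 3, and C1qc at least 14.1-fold and 70.2-fold.

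Among 18 leukocyte markers, 15 rose (16 adjusted over the list alone), with a median log2 change of 4.23, or 4.01 with undetected members at their bound. The camera test gave an adjusted p of 7.62e-12, and an adjusted p of 0.116 with an estimated correlation. The markers include Ptprc, the pan-leukocyte antigen (at least 2.53-fold), Csf1r, the receptor for macrophage colony-stimulating factor (32.3-fold), Tyrobp (39.5-fold) and Adgre1, the F4/80 antigen (41.4-fold). These folds average in 4T1 replicate 1. Without it, the log2 changes of Csf1r, Tyrobp and Adgre1 went from 5.01, 5.30 and 5.37 to 5.62, 6.38 and 6.53, with bounds of at least 19.0-fold, 34.5-fold and 66.8-fold. Adgre1 rose 25.8-fold without 4T1 replicate 2, and Csf1r 55.3-fold without 4T1-PE replicate 3. Among 29 epithelial genes, 24 fell (26 over the list alone, median -1.31, camera adjusted p = 7.05e-13, adjusted p = 0.131 with an estimated correlation). Keratin 18 (Krt18) was 3.57-fold lower at 11.07 ± 0.47, still bright, and the tight junction gene Tjp1 and the protease inhibitor genes Spint1 and Spint2 were 2.98-fold, 3.24-fold and 3.08-fold lower. Among 19 mesenchymal genes, 10 fell and 3 rose (the same numbers adjusted over the list alone, median -1.30, or -0.72 at the bounds). The list passed with an adjusted p of 0.0278, and had an adjusted p of 0.603 with an estimated correlation. Twist1, Ccn2 and Postn fell, while Zeb2, which myeloid cells also express, rose 6.62-fold. The call for the list was lost without 4T1 replicate 2 (adjusted p = 0.0505) or 4T1-PE replicate 3 (adjusted p = 0.0923), and the range over all alternatives is 0.00138 to 0.603.

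Synthesis of eicosanoids, the lipid mediators that 5-lipoxygenase and the cyclooxygenases make from arachidonic acid, is part of the question the series names. The 5-lipoxygenase gene Alox5 was not analysed here, and Alox12 and Alox15, outside the rule for named genes, were detected on 0 of 16 arrays. Alox5ap, which encodes the 5-lipoxygenase-activating protein, rose 34.8-fold in 4T1-PE (log2 intensity 6.59 ± 2.32 to 11.71 ± 0.77, SD, n = 3, adjusted p = 0.00109). Its value was 9.28 in 4T1 replicate 1, the sample with Lyz2 signal, and 5.31 and 5.19 in the others. Alox5ap rose at least 48.3-fold without that sample, and rose 22.3-fold and 21.4-fold without replicate 2 or 3. Hpgds and Tbxas1, the prostaglandin D and thromboxane synthases, rose, Hpgds at least 4.73-fold and Tbxas1 8.22-fold (at least 5.81-fold, with a log2 change of 3.71, without 4T1 replicate 1), and Mgst2, a microsomal glutathione transferase, rose 4.86-fold. The leukotriene C4 synthase gene Ltc4s had a log2 change of 2.79 (SE 0.91, adjusted p = 0.049), with values of 10.28, 8.76 and 5.98 in the 3 treated samples. The log2 change was 1.83 and 3.98 without 4T1-PE replicate 1 or 3. The call held in 11 of 26 alternatives, with adjusted p between 0.00242 and 0.211. Lta4h, the leukotriene A4 hydrolase gene, had a log2 change of -0.11 (adjusted p = 0.807). Its second passing probe had the opposite sign, from 5.34 ± 0.16, undetected, to 6.08 ± 0.42 (SD, n = 3). Of 19 genes on the list, 9 rose (9 over the list alone, median 0.93, camera adjusted p = 0.00137, adjusted p = 0.116 with an estimated correlation). Over 29 settings, the main fit included, the list passed in 27. The adjusted p of camera or fry lay between 3.76e-05 and 0.865. Ppara was detected on 0 of 16 arrays, and the 18 tested PPARalpha targets did not pass as a list (adjusted p = 0.103). Of these, Acaa1a, Ucp2 and Ech1 rose 1.89-fold, 3.38-fold and 1.67-fold. Each of the 3 calls was lost without any of 3 of the 12 samples. These were 4T1 replicate 1 or 2 or 4T1-PE replicate 2 for Acaa1a (highest adjusted p = 0.0624), 4T1 replicate 3 or 4T1-PE replicate 1 or 2 for Ucp2 (0.0831), and 4T1 replicate 2 or 3 or 4T1-PE replicate 1 for Ech1 (0.102).

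Of 4 chemokine receptor genes tested, 3 rose in 4T1-PE, among them Cxcr4 (15.3-fold) and Ccrl2 (at least 2.88-fold). The list had a median log2 change of 3.04, or 2.12 at the bounds, and all 3 passed over the list alone (camera adjusted p = 0.0093, adjusted p = 0.116 with an estimated correlation). Chemokines and cytokines went both ways, with 9 rises and 5 falls among 31 (11 and 6 over the list alone, adjusted p = 0.467). The macrophage inflammatory protein genes Ccl3 and Ccl4 rose 42.8-fold and 42.1-fold, Ccl9 rose 13.2-fold, and Cxcl14 rose at least 6.70-fold. Without 4T1 replicate 1, Ccl3, Ccl4 and Ccl9 rose at least 38.0-fold, 43.9-fold and 7.78-fold, with log2 changes of 6.67, 6.79 and 4.397. Without 4T1 replicate 2 or 3, Ccl3 rose 28.1-fold and 27.5-fold and Ccl4 25.7-fold and 26.4-fold. Hypoxia and glycolysis genes passed as a list, with 6 rises among 33 (5 over the list alone, median 0.37, adjusted p = 0.0287, adjusted p = 0.678 with an estimated correlation). The glucose transporter gene Slc2a3 rose 14.5-fold (at least 10.9-fold, with a log2 change of 4.65, without 4T1 replicate 1) and the kinase gene Pdk1 3.02-fold. The call for the list was lost without 4T1 replicate 1 (adjusted p = 0.138), 4T1-PE replicate 2 (0.098) or 4T1-PE replicate 3 (0.128). It held in 23 of 29 settings, the main fit included.

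The other lists did not pass in 4T1-PE. Of 40 interferon response genes, Lgals3bp rose (log2 change 1.32) and Isg20 was 2.57-fold lower (median 0.03, adjusted p = 0.892). Adjusted over the list alone limma called 0 of them, and 6 had an unadjusted p under 0.05. The call for Lgals3bp was lost without 4T1 replicate 1 or 3 or 4T1-PE replicate 1 or 2 (highest adjusted p = 0.145), and that for Isg20 without any 1 of 5 samples, namely all of 4T1 and 4T1-PE replicates 1 and 3 (highest adjusted p = 0.104). Of 24 class I antigen presentation genes, H2-K1 rose 13.1-fold and Psmb9 4.00-fold, while H2-Q8 and H2-Q7 fell (adjusted p = 0.962). The call for H2-Q7 was lost without 4T1 replicate 2 or 3 or 4T1-PE replicate 1 (highest adjusted p = 0.0615). Class I genes are near-identical copies, and a probe may report more than 1 of them. The cathepsin genes Ctss, Ctsz and Ctsb rose 24.6-fold, 3.64-fold and 3.44-fold among 27 matrix proteases and inhibitors (Ctss at least 25.5-fold, with a log2 change of 5.46, without 4T1 replicate 1), and Adam12 fell (list adjusted p = 0.949, median -0.36 and mean 0.05). Gstm1 rose at least 6.59-fold and the ferritin gene Fth1 rose 2.39-fold among NRF2 and glutathione genes (adjusted p = 0.131). Saa3, an acute-phase gene, rose 31.8-fold and Vcam1 was 3.15-fold lower among NF-kappaB targets (adjusted p = 0.949, median -0.22 and mean 0.06). Among 57 cell cycle genes, E2f2 rose 4.37-fold (adjusted p of the list = 0.949). Kdelr3, a receptor that retrieves proteins to the endoplasmic reticulum, fell 2.61-fold within the diphthamide and exotoxin A pathway (list adjusted p = 0.949). Vldlr fell in the unfolded protein list (adjusted p = 0.892). Cholesterol synthesis (adjusted p = 0.485, 0 genes called by limma and 1 with an unadjusted p under 0.05), fibroblast markers (0.949, 0 called and 1 with an unadjusted p under 0.05) and endothelial markers (0.892) did not pass either. Of the endothelial genes, Vwf rose at least 5.09-fold (at least 7.98-fold and 2.41-fold without 4T1-PE replicate 2 or 3) and Flt1 and Eng were 3.00-fold and 2.71-fold lower, so that the median was -0.31 and the mean 0.24. With arrays only median-scaled, 927 genes rose and 387 fell, relative to a median of all genes of 0.19, and without 4T1-PE replicate 1 there were 1071 changed genes instead of 1665.

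The second comparison put the same question to 4T1.2. Several myeloid transcripts that no untreated array detected were bright after treatment. Lyz2 was on 0 of 5 untreated arrays and at 14.57 ± 0.26 (SD, n = 3) in 4T1.2-PE, a rise of at least 368.5-fold (adjusted p = 4.3e-05). Laptm5 rose at least 258-fold, Ccl4 at least 134-fold, Ccl3 at least 117-fold, Fcer1g at least 106.0-fold, and Coro1a, a leukocyte actin-binding gene, at least 103-fold. Adgre1, the inhibitory Fc receptor gene Fcgr2b and the lectin gene Clec4d rose at least 100.9-fold, 70.2-fold and 61.6-fold. Several transcripts bright in untreated 4T1.2 fell to background or near it. The receptor tyrosine kinase gene Axl was 255-fold lower, from 13.40 ± 0.35 to 5.40 ± 0.67, and was detected on 1 of 4 treated arrays (adjusted p = 1.87e-08). Keratin 8 (Krt8) fell from 12.76 ± 0.54 to 4.95 ± 0.21, at least 98.4-fold (adjusted p = 6.24e-09), and Krt18 at least 91.7-fold. Hoxa5, Endod1, the thrombin receptor gene F2r and the integrin gene Itga3 were bright in every untreated sample and detected on none of the 4 treated arrays, with falls of at least 85.6-fold, 68.8-fold, 67.5-fold and 53.6-fold. Wfdc2 and Serpinh1, a collagen chaperone gene, were 187-fold and 156-fold lower. H2-D1 was 235-fold lower and is reported as uncertain, being one of the class I copies. Without 4T1.2-PE replicate 1, Wfdc2 was 103-fold lower. Without 4T1.2-PE replicate 3, Wfdc2 was 314-fold and H2-D1 at least 211-fold lower, and Ccl4 and Ccl3 rose at least 85.2-fold and 68.7-fold. In all, 1450 genes rose and 1532 fell, 166 and 173 of them at least 16-fold. The samples did not overlap for 45.6% of genes, against 10% by chance.

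Leukocyte markers rose for 15 of 18 genes (16 over the list alone, median 5.31, or 4.23 at the bounds, camera adjusted p = 3.08e-08, adjusted p = 0.345 with an estimated correlation). Csf1r rose at least 31.8-fold and Tyrobp at least 42.3-fold. Epithelial genes fell for 17 of 29 (18 over the list alone, median -1.34, or -0.99 at the bounds, camera adjusted p = 5.38e-07, adjusted p = 0.357 with an estimated correlation). Krt7 fell at least 73.6-fold and Tjp1 at least 3.56-fold, and neither was detected after treatment. Mesenchymal genes fell for 9 of 19 and rose for 2, the same numbers over the list alone (median -0.68, adjusted p = 0.00291, adjusted p = 0.357 with an estimated correlation). Twist1 was 9.02-fold lower, and the matrix genes Sparc and Col5a1 at least 11.3-fold and 21.0-fold. The fibroblast markers Pdgfra and Fbln2 fell at least 11.9-fold and 2.93-fold (3 tested, 3 past the threshold over the list alone, median -2.83, or -1.55 at the bounds, adjusted p = 0.0176, adjusted p = 0.345 with an estimated correlation).

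**Figure D1:**
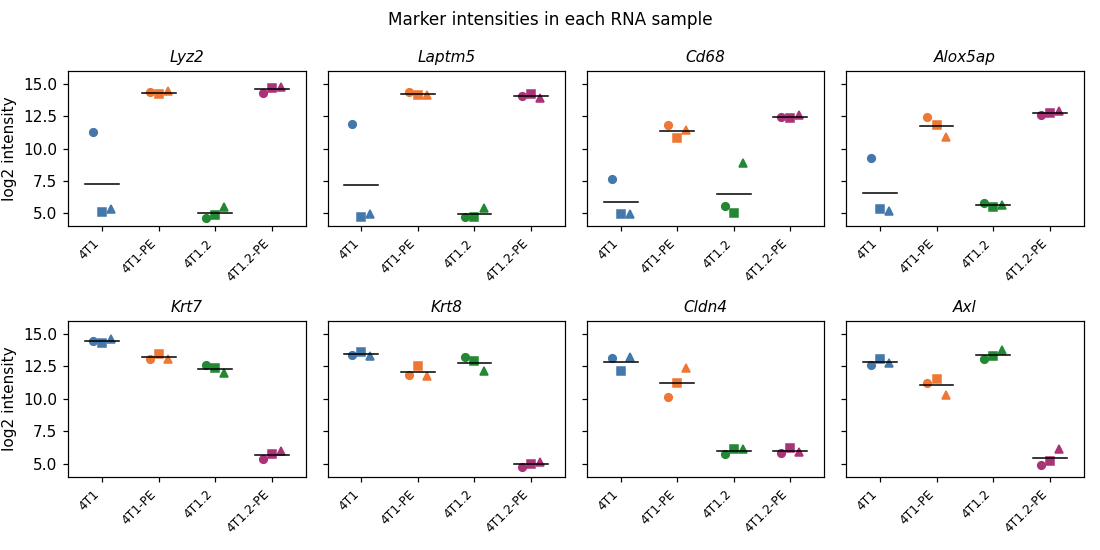
Log2 intensity of 8 genes in the 12 RNA samples, grouped along the horizontal axis by culture, with a circle, square or triangle for replicate 1, 2 or 3 and a line at the group mean. Lyz2 lay above 14 in all 6 treated samples and at 11.30 in 4T1 replicate 1, and Krt8 lay between 4.73 and 5.15 in 4T1.2-PE against 11.78 to 12.52 in 4T1-PE.

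Interferon response genes fell in 33 of 40 cases (34 over the list alone, median -2.07, camera adjusted p = 1.28e-08, adjusted p = 0.595 with an estimated correlation). Isg15, a ubiquitin-like protein gene, fell at least 44.1-fold (at least 26.4-fold without 4T1.2 replicate 3), Oasl1 at least 8.63-fold and Isg20 at least 6.32-fold. Eif2ak2, the kinase gene PKR, was 4.99-fold lower. Class I antigen presentation genes fell for 10 of 24 and rose for 1, as over the list alone (median -0.74, adjusted p = 0.00649, adjusted p = 0.697 with an estimated correlation). H2-Q8 and H2-Q7 fell at least 8.15-fold and 7.90-fold, H2-K1 rose 16.3-fold, and B2m, outside the rule for named genes, had a log2 change of -0.50 (adjusted p = 0.155). Cholesterol synthesis genes rose for 9 of 20 (10 over the list alone, median 1.13, adjusted p = 0.00649, adjusted p = 0.745 with an estimated correlation). The demethylation enzyme gene Msmo1 rose 5.19-fold, Lss 4.08-fold, Hmgcs1 2.53-fold and Mvd at least 3.25-fold.

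In the eicosanoid pathway, Alox5ap rose at least 103-fold in 4T1.2-PE, from 5.66 ± 0.16 to 12.74 ± 0.18 (SD, n = 3, adjusted p = 2.66e-05). Hpgds rose at least 7.16-fold, while the phospholipase genes Pla2g6 and Pla2g7 were 4.33-fold and at least 1.45-fold lower. With 8 rises and 6 falls among 19 the list did not pass (9 and 6 over the list alone, adjusted p = 0.549). Ltc4s had a log2 change of 2.88 (SE 0.91, adjusted p = 0.0261, at least 4.46-fold), with sample values of 9.68, 8.33 and 6.60, and was at least 2.67-fold and 7.77-fold higher without 4T1.2-PE replicate 1 or 3. That call held in 18 of 26 alternatives, with adjusted p between 0.00115 and 0.11. Lta4h had a log2 change of -0.34 (adjusted p = 0.318). Its second probe again had the opposite sign and moved more, from 5.35 ± 0.11 to 6.59 ± 0.37 (SD, n = 3), undetected before treatment. Among PPARalpha targets, Acsl1, Ucp2 and Acaa1a rose 4.91-fold, 2.99-fold and 1.70-fold and Acadvl was 1.78-fold lower (list adjusted p = 0.309). The calls for Ucp2 and Acaa1a were lost without 4T1.2 replicate 1 or 4T1.2-PE replicate 1 or 2 (highest adjusted p = 0.0638 and 0.0964).

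The remaining lists did not pass in 4T1.2-PE. Chemokine receptors had an adjusted p of 0.0632, with 3 of 4 up, among them Cxcr4 (12.9-fold) and Ccrl2 (4.49-fold, and at least 4.81-fold, with a log2 change of 2.85, without 4T1.2 replicate 3). Of 31 chemokines and cytokines, 13 rose and 9 fell (adjusted p = 0.425). Ccl9 rose at least 18.7-fold, and Il23a and Tgfb3 fell at least 6.64-fold and 2.40-fold and Cx3cl1 from 9.46 ± 0.26 to undetected. Matrix proteases showed 8 rises and 12 falls (adjusted p = 0.425). The membrane collagenase gene Mmp14 was 87.6-fold lower and Plat and Ctsh fell, while Ctss rose at least 25.2-fold. Among NF-kappaB targets (adjusted p = 0.973, median -0.05 and mean 0.06), Vcam1 fell at least 31.8-fold and Traf1 fell 12.3-fold, and the neutrophil chemokine gene Cxcl2 rose at least 45.9-fold (at least 71.1-fold and 25.2-fold without 4T1.2-PE replicate 1 or 3). In hypoxia and glycolysis (adjusted p = 0.681), Aldoc and Slc2a3 rose at least 15.0-fold and 15.5-fold, and Car12 and P4ha2 fell. Among NRF2 and glutathione genes (adjusted p = 0.681, median 0.41 and mean -0.06), Gstp1 was 22.8-fold lower, and Nqo1, Aldh3a1 and Gsta4 fell to undetected. Kdelr3 fell at least 15.8-fold in the exotoxin A pathway list (adjusted p = 0.669, median 0.23 and mean -0.07). In the unfolded protein list (adjusted p = 0.973), Chac1 was 8.94-fold (5.01-fold without 4T1.2-PE replicate 2) and Ddit4 4.87-fold lower and Sdf2l1 rose 4.29-fold. Endothelial markers had an adjusted p of 0.425, with Flt1 down at least 6.35-fold and Vwf up at least 5.15-fold. Cell cycle genes had a median of -0.55 and an adjusted p of 0.278, which became 0.0206 with the replicate number as a block. Mvd, which had a log2 change of 1.07 in 4T1 (adjusted p = 0.118), passed there with that block (adjusted p = 0.0397).

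Changes after TARC-PE38 in both lines were compared next. They share no array. In all, 738 genes rose in both lines, against 151.8 expected for independent lists, and 645 fell in both, against 151.2. Another 7 genes were called in opposite directions. The changes correlated across genes with Pearson's r = 0.814 and Spearman's rho = 0.740 over 8187 genes, which are not independent replicates. Of the genes that rose in 4T1-PE, 86.1% also rose in 4T1.2-PE, and of those that fell 79.8% also fell. Among genes called the same way, the change in 4T1 was a median 0.713 of that in 4T1.2 on the log2 scale.

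**Figure D2:**
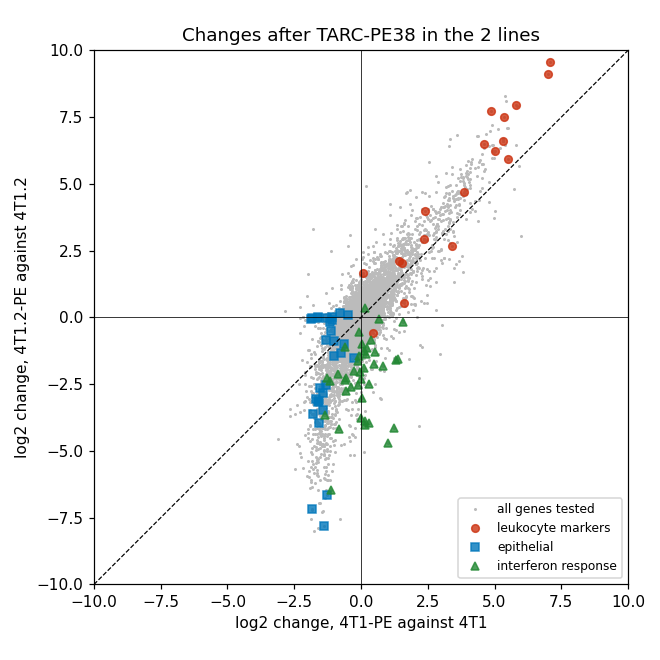
Log2 change after TARC-PE38 in 4T1 (horizontal axis) and 4T1.2 (vertical axis), 1 point per gene, with leukocyte markers, epithelial genes and interferon response genes coloured. Across genes r was 0.814, with leukocyte markers high in both lines (medians 4.23 and 5.31) and interferon response genes low in 4T1.2 (median -2.07) against a median of 0.03 in 4T1.

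The untreated lines were set against each other. Rsad2, which encodes the interferon-induced protein viperin, was 57.3-fold higher in 4T1.2 at 11.45 ± 1.84 (SD, n = 3, adjusted p = 0.00263) and Cmpk2 at least 21.7-fold higher. The creatine kinase gene Ckb was 36.2-fold, Arap3 26.2-fold and the small heat shock protein gene Hspb1 at least 17.8-fold higher. Rsad2 was 93.3-fold and Cmpk2 at least 33.2-fold higher without 4T1.2 replicate 2, and 27.9-fold and at least 11.1-fold without 4T1.2 replicate 3. Arap3 was at least 19.4-fold higher, with a log2 change of 5.53, without 4T1 replicate 1. The tight junction gene Cldn4 was 115-fold lower (12.84 ± 0.61 to 6.00 ± 0.25, adjusted p = 1.46e-06). Entpd3, Rab25 and Fermt1 were bright in 4T1 and not detected in 4T1.2, at least 35.4-fold, 32.2-fold and 27.2-fold lower. In all, 394 genes were higher and 385 lower in 4T1.2.

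Interferon response genes were higher in 4T1.2 for 24 of 40 (36 over the list alone, median 2.02, or 1.96 at the bounds, camera adjusted p = 1.89e-22, adjusted p = 0.297 with an estimated correlation). Their level differed among 4T1.2 samples, and Rsad2 stood at 10.79, 10.05 and 13.53 in replicates 1, 2 and 3. Replicate 3 also had the macrophage transcript Cd68 at 8.88, against 5.55 and 5.05, as seen after the values were examined. Other such transcripts, Lyz2, Laptm5, Csf1r, C1qb and Alox5ap, were undetected on all untreated 4T1.2 arrays and stood at 5.52, 5.40, 4.72, 4.69 and 5.64 in replicate 3. Class I genes were higher for 9 of 24 (12 over the list alone, median 1.04, adjusted p = 9.45e-08, adjusted p = 0.345 with an estimated correlation). Epithelial genes were lower for 16 of 29 (19 over the list alone, median -1.53, or -1.21 at the bounds, adjusted p = 2.76e-19, adjusted p = 0.213 with an estimated correlation). Besides Cldn4 and Rab25 they include the splicing factor gene Esrp1 and the transcription factor gene Grhl2, both named after their values were seen, with log2 changes of -5.59 and -3.71. Hypoxia and glycolysis genes showed 5 higher and 2 lower among 33 (8 and 3 over the list alone, median 0.48, adjusted p = 0.0049, adjusted p = 0.597 with an estimated correlation). Eicosanoid synthesis had 5 higher among 19 (6 over the list alone, median 0.04, adjusted p = 0.016, adjusted p = 0.246 with an estimated correlation), among them Mgst2, named after its value was seen, with a log2 change of 4.06. This list passed in 27 of 29 settings, the main fit included, with an adjusted p of camera or fry between 0.00353 and 0.922. NRF2 and glutathione genes had 4 higher among 33 (6 over the list alone, median 0.21, adjusted p = 0.016, adjusted p = 0.674 with an estimated correlation). Cholesterol synthesis had 2 lower among 20 (2 over the list alone, median -0.56, adjusted p = 0.016, adjusted p = 0.794 with an estimated correlation), a call lost without 4T1 replicate 2 (adjusted p = 0.503) or 4T1.2 replicate 3 (0.056). The cholesterol call held in 23 of 29 settings, the main fit included. The replicate block called 1575 genes, 759 higher and 816 lower, instead of 779, and gave cell cycle genes an adjusted p of 0.0251 in place of 0.225. There were 455 changed genes without 4T1 replicate 1 (903 with the block as well), 480 without 4T1 replicate 3 and 512 without 4T1.2 replicate 1.

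Between the treated cultures, keratin transcripts were among those with the largest deficit in 4T1.2-PE. Krt7 was at least 133-fold lower (13.19 ± 0.22 to 5.68 ± 0.29, SD, n = 3, adjusted p = 3.29e-09), Krt8 at least 59.8-fold and Krt14 at least 54.3-fold. Wfdc2 was 114-fold and Fbln2, an extracellular matrix gene, at least 28.3-fold lower. Krt14 was already low before treatment in 4T1.2, at 7.18, 5.43 and 6.90, against 12.58, 11.95 and 11.89 in untreated 4T1. The genes with the largest excess in 4T1.2-PE were the signalling adaptor gene Stap1 (7.13-fold, adjusted p = 0.00384), Tnf (6.38-fold), St3gal5 (6.29-fold), the niacin receptor gene Hcar2 (at least 2.86-fold) and Slc28a2 (4.06-fold). The call for Tnf was lost without 4T1-PE replicate 2 or 3 (highest adjusted p = 0.0764) and that for Slc28a2 without 4T1-PE replicate 2 (adjusted p = 0.0687). Without 4T1.2-PE replicate 3 the excess was 4.52-fold for Stap1, 3.12-fold for Tnf and 2.46-fold for Slc28a2, and the deficit of Wfdc2 191-fold. Without 4T1.2-PE replicate 1 that of Wfdc2 was 63.0-fold, and without replicate 2 the excess of Tnf was 9.80-fold. In all, 113 genes were higher and 562 lower.

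Epithelial genes were lower in 4T1.2-PE for 23 of 29 (26 over the list alone, median -2.35, or -1.07 at the bounds, camera adjusted p = 3e-31, adjusted p = 0.0548 with an estimated correlation). Mesenchymal genes were lower for 8 of 19 and higher for 1 (10 and 1 over the list alone, median -0.87, or -0.16 at the bounds, adjusted p = 0.000241, adjusted p = 0.269 with an estimated correlation), and fibroblast markers for 1 of 3 (2 over the list alone, median -1.13, or -0.34 at the bounds, adjusted p = 0.0193, adjusted p = 0.164 with an estimated correlation). Leukocyte markers passed as a list with a median of 0.60 (adjusted p = 0.0398, adjusted p = 0.782 with an estimated correlation), although limma called 0 of the 18 singly and 2 had an unadjusted p under 0.05. That call was lost without 4T1-PE replicate 2 (adjusted p = 0.0503) or 3 (0.104) or 4T1.2-PE replicate 3 (0.085). It held in 20 of 28 settings, the main fit included. Interferon response genes had a median of 0.01 between the treated cultures (adjusted p = 0.831). The replicate block called 1082 genes, 335 higher and 747 lower, and median scaling gave 17 higher and 616 lower, relative to a median of all genes of -0.25. There were 415 genes without 4T1-PE replicate 2 and 424 with only these 2 groups in the fit, instead of 675.

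Finally, the change after treatment was compared between the lines by the difference of the changes. It was more positive in 4T1.2 for 114 genes and more negative for 443. The largest positive differences belonged to Il1a, Celf2, Gadd45b, Atg9b and Cask, whose levels were lower in untreated 4T1.2 than in 4T1. Il1a, which encodes interleukin 1 alpha, went from undetected (5.06 ± 0.02) to 8.37 ± 1.76 in 4T1.2 and from 10.94 ± 0.64 to 9.14 ± 0.62 in 4T1 (difference 5.09, SE 0.96, adjusted p = 0.00602). Celf2 and Cask had differences of 4.72 and 3.52. Gadd45b, a stress-induced gene, had a difference of 3.63 (adjusted p = 0.0217), a call lost without 4T1 replicate 1 or 3, 4T1-PE replicate 3 or 4T1.2 replicate 2 (highest adjusted p = 0.0594). Over all its alternatives the adjusted p lay between 0.00445 and 0.0786. The largest negative differences were those of Wfdc2 (-6.76), Krt8 (-6.41), H2-D1 (-6.26), Ly6a (-6.25) and Axl (-6.23). Differences of changes are fitted values and not bounds, also for genes undetected in a group, such as Krt8 and Ly6a. Wfdc2 had a log2 change of -0.79 in 4T1 (adjusted p = 0.4) and of -7.55 in 4T1.2. Without 4T1.2-PE replicate 1 or 3, the differences were 5.83 and 4.12 for Il1a, 4.25 and 2.74 for Gadd45b and -5.90 and -7.51 for Wfdc2, and that of H2-D1 was -7.07 without replicate 3. The difference of Ly6a was -7.002 without 4T1-PE replicate 1, and -7.08 and -5.25 without 4T1.2 replicate 1 or 3. Ly6a, the stem cell antigen Sca-1, was undetected in 4T1 and at 9.93 ± 1.85 in 4T1.2 before treatment.

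Interferon response genes fell more in 4T1.2 for 17 of 40 (25 over the list alone, median difference -2.01, camera adjusted p = 2.33e-15, adjusted p = 0.417 with an estimated correlation). As given above, these genes were higher in untreated 4T1.2 than in untreated 4T1, with like medians in the treated cultures. The difference therefore goes with the level before treatment, which follows from these medians and names no cause. A gene near background in untreated 4T1 had no room to fall, but how many were so low was not counted. Isg15 stood at 7.27, 8.18 and 8.54 there and was not at background. Class I genes fell more in 4T1.2 for 4 of 24 (5 over the list alone, median -0.85, adjusted p = 3.95e-05, adjusted p = 0.417 with an estimated correlation). Mesenchymal genes showed 7 more negative and 1 more positive among 19 (8 and 2 over the list alone, median -0.998, adjusted p = 0.000219, adjusted p = 0.417 with an estimated correlation). Fibroblast markers had 2 of 3 more negative (3 over the list alone, median -2.77, adjusted p = 0.000442, adjusted p = 0.0806 with an estimated correlation). Cholesterol synthesis had a median of 0.87 and 1 gene past the threshold (2 over the list alone, adjusted p = 0.00254, adjusted p = 0.747 with an estimated correlation), a call lost without 4T1 replicate 2 (adjusted p = 0.11). Hypoxia and glycolysis had 2 more negative and 1 more positive (7 and 1 over the list alone, median -0.40, adjusted p = 0.0193, adjusted p = 0.595 with an estimated correlation), lost without 4T1 replicate 1 (0.0934) or 4T1.2-PE replicate 1 (0.13). Of 28 settings, the main fit included, cholesterol synthesis passed in 25 and hypoxia and glycolysis in 23. Epithelial genes did not pass for the difference of the changes (camera adjusted p = 0.109). No list call in any of the 5 contrasts held with an estimated correlation. The replicate block called 963 genes, 303 and 660 by direction, instead of 557, and gave adjusted p of 0.0177 for cell cycle (0.228 without it) and 0.0357 for matrix proteases (0.0537 without it). Median scaling gave 38 more positive and 423 more negative, relative to a median of all genes of -0.16, and the z-scores 356 genes.

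**Figure D3:**
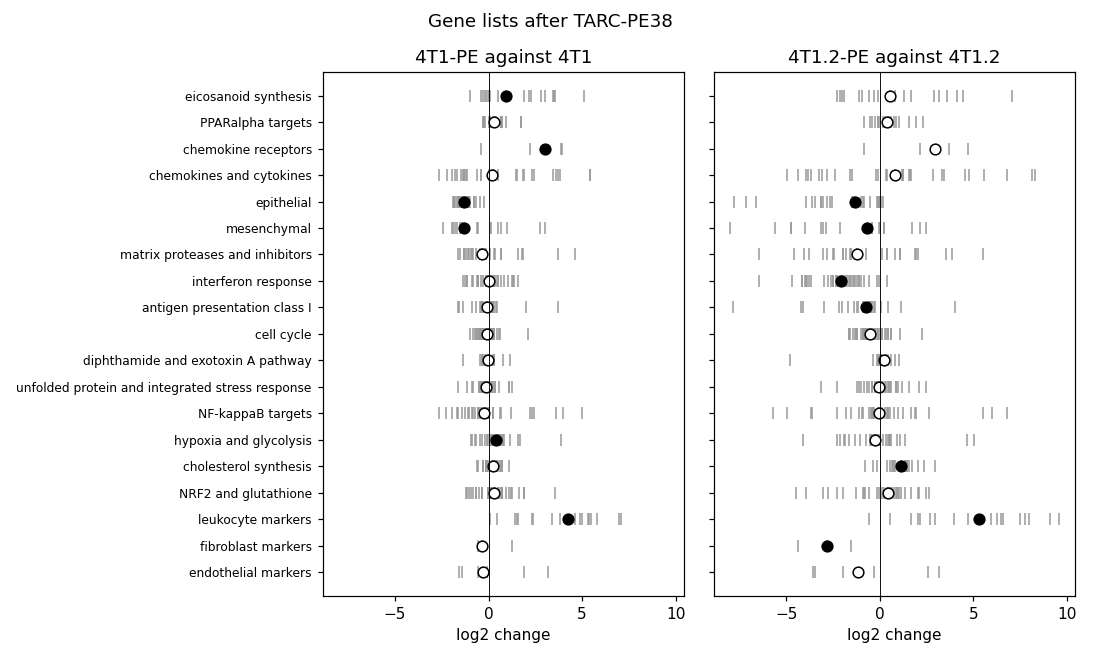
Log2 change of the members of each gene list (ticks) and their median (circle, filled where the camera adjusted p at the preset correlation was under 0.05) after TARC-PE38 in 4T1 and in 4T1.2. Leukocyte markers lay furthest to the right (medians 4.23 and 5.31), and epithelial genes had medians of -1.31 and -1.34.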

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

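The following were chosen after the results they bear on had been seen. They are the test with macrophage, T cell, B cell, erythroid and megakaryocyte markers and that of the leukocyte list under median scaling. The set of genes matched in level and the division of splits by exchanged labels were also chosen then.

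Results that differed between the lines by the test of the difference were the following, as log2 differences of the change after TARC-PE38 (4T1.2 minus 4T1). Altogether 557 genes differed. Il1a (5.09), Celf2 (4.72), Gadd45b (3.63), Atg9b (3.604) and Cask (3.52) were more positive in 4T1.2. Wfdc2 (-6.76), Krt8 (-6.41), H2-D1 (-6.26), Ly6a (-6.25) and Axl (-6.23) were more negative. Median differences of the lists that passed were -2.77 for fibroblast markers, -2.01 for interferon response, -0.998 for mesenchymal genes, -0.85 for class I antigen presentation, -0.40 for hypoxia and glycolysis and 0.87 for cholesterol synthesis. With an estimated correlation none of these 6 calls held (adjusted p = 0.0806, 0.417, 0.417, 0.417, 0.595 and 0.747 in that order), and those for hypoxia and glycolysis and for cholesterol synthesis were also lost without single samples. The difference of interferon response genes goes with their higher level in untreated 4T1.2. Of 100 drawn splits of the 12 samples, 7, the real one included, gave at least 557 genes, and the highest other gave 3342. Of the 6 others as large, 5 exchange all 3 treatment labels of 4T1.2, which turns a difference of changes into their sum. A high count there points to the structure of the samples and does not measure chance, so this count leaves chance open. Of the 54 splits that do not exchange most of these labels, the real one included, 1 other was as large, with 598 genes.

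The splits were run in the fit without the replicate block. For the 4 comparisons of a pair of groups, the 6 samples make 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes as the real one. It gave 1665 genes in 4T1-PE against 4T1 (highest other 0), 2982 in 4T1.2-PE against 4T1.2 (0), 779 in 4T1.2 against 4T1 (0) and 675 in 4T1.2-PE against 4T1-PE (9).

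Of 18 leukocyte markers 15 rose in each line, and of 29 epithelial genes 24 fell in 4T1-PE and 17 in 4T1.2-PE. Of 39 macrophage markers on the array, 71.8% rose at least 2-fold in both lines, against 4.55% of 44 T cell, B cell, erythroid and megakaryocyte markers. Cells of a macrophage type in the cultures would give such a rise. Of the 39, 25 were detected on an untreated array, 3 on all 9 of them, and 14 are held by a fixed list. Under median scaling the leukocyte median stayed at 4.39 in 4T1, so the rise did not need quantile normalization. Scaling could hardly have removed so large a rise, so that test shows no more. Y-linked genes were detected on no array (0 of 7). This cannot decide about cells from a male animal, as no sample of known male cells shows that the probes work. Whether tumour cells took on a macrophage-type state or cells of a macrophage type overgrew the culture was not tested. Lyz2, an abundant marker of macrophages, stood at 14.32 ± 0.11 in 4T1-PE and 14.57 ± 0.26 in 4T1.2-PE (SD, n = 3).

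Samples of 4T1-PE lay between 4T1 and 4T1.2-PE. A mixture of 4T1 cells with cells like those of 4T1.2-PE would give 1 share per sample, whichever genes it is computed from. From 151 risen and 174 fallen genes the shares were 74.2% and 78.1% in replicate 1, 43.7% and 56.7% in replicate 2 and 52.4% and 65.4% in replicate 3. These shares are medians over genes. Their largest difference, 13.0 points, lay between the 10 points set in advance for a mixture and the 20 points set against it. A mixture thus cannot be told apart from a partial change of all cells. Single genes differed widely within a sample. The quartiles for risen genes were 52.1% and 89.4%, 31.5% and 57.7%, and 29.2% and 76.5% in replicates 1, 2 and 3. Those for fallen genes were 73.6% and 82.7%, 47.0% and 65.6%, and 53.0% and 71.4%. By limma, 6 genes were called (adjusted p under 0.05) outside the range against both 4T1 and 4T1.2-PE. They were Ptgs1, Krt17, Slc29a3 and Cxcl14 above it and Pxk and Col4a5 below it, named after their values were seen. Genes whose 4T1-PE mean lay outside the range without both calls were not counted, so 6 is not the number of all such genes.

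Several leukocyte transcripts were detected in 4T1 replicate 1 without treatment, with Lyz2 at 11.30 against 5.14 and 5.32 in the other 4T1 samples. Of 116 genes at least 16-fold higher in 4T1-PE than in 4T1 replicates 2 and 3 alone, 94.0% were above replicates 2 and 3 on both arrays of this sample, against 36.2% of 116 other genes of like level in replicates 2 and 3 (median 5.14, against 4.93) that did not rise. As the risen genes were chosen as low in replicates 2 and 3, some excess follows from the choice. The median log2 excess of replicate 1 was 2.04 and 0.08, and its share of the treated level a median 9.41% (quartiles 6.10% and 14.6%). These values are consistent with carry-over of RNA or cells of the treated kind, and a few cells of that kind in the untreated 4T1 culture itself would give the same values and stay open.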

How the results depend on the processing

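The alternative without 4T1 replicate 1 and with the block was chosen after seeing the data. Over 30 alternatives, 5013 values of named genes counted as the same, 148 as weaker, 6 as stronger and 0 as reversed. For gene lists, 2468 counted as the same, 70 as weaker, 80 as stronger and 3 as reversed. Direction was compared only for results called in the main fit. An uncalled result that changed sign counted as the same or, if it became called, as stronger. Of 192 gene calls, 26 were lost under at least 1 alternative that tested them. A result that an alternative did not test was left out and not counted as lost. Detection on all 16 arrays tested only 29 of the 198 named gene results. The list-test alternatives and the 2-fold minimum gave no values of named genes. Detection on all 16 arrays removes by construction each gene silent in 1 group. It left 413 genes changed in 4T1-PE, 1302 in 4T1.2-PE, 308 between the lines, 67 between the treated cultures, 43 that differed in their change, 326 shared and a correlation of 0.705, with 4 lists past the test over both treatment comparisons instead of 13. The mesenchymal median turned to 0.11 in 4T1-PE, 0.20 in 4T1.2-PE and 0.72 between the treated cultures. Between the lines, median scaling gave 411 genes, array weights 1321 and the replicate block 1575. Between the treated cultures, the block gave 1082, the added alternative 1014 and only these groups 424. For the difference of the changes, the block gave 963 and the z-scores 356. Camera with an estimated correlation called 0 lists, against 13 at the preset one. In the treatment comparisons the block gave 2424 genes in 4T1-PE (1151 higher and 1273 lower), 3840 in 4T1.2-PE (1869 higher and 1971 lower) and 1923 shared, instead of 1665, 2982 and 1383. Among the named genes and lists, the block changed no call except for Mvd, cell cycle genes and matrix proteases. Where construction does not show it, the cause was not tested.

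Leaving out 1 sample gave 1071 to 1900 genes in 4T1-PE, 2506 to 3044 in 4T1.2-PE, 455 to 991 between the lines, 415 to 716 between the treated cultures and 415 to 583 that differed in their change. It gave 928 to 1512 shared genes, correlations of 0.785 to 0.819 and 12 to 15 lists. No slide term was run, as the slides are not known. Signal over background limits dim probes, whose changes the offset understates.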

Other observations

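Class I genes did not move together in 4T1.2-PE. H2-K1 rose with a log2 change of 4.02 while H2-D1 went from 13.77 to 5.90, and B2m, the light chain all class I molecules share and named after its value was seen, stood at 13.95 ± 0.27 (SD, n = 3). These genes are near-identical, and a probe can read more than 1 of them.

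Some macrophage transcripts differed among treated samples, as seen after the data were examined. In 4T1-PE, C1qa stood at 10.24, 9.55 and 5.65 in replicates 1, 2 and 3, and in 4T1.2-PE at 9.04, 9.18 and 5.52. Aif1 stood at 9.58, 8.45 and 5.03 in 4T1-PE and at 8.94, 8.58 and 5.30 in 4T1.2-PE. Lyz2 lay above 14 in all 6. Along the third principal component, with 9.13% of the variance, replicate 3 of 4T1-PE and 4T1.2-PE lay at 33.5 and 44.4, and the other treated samples between -25.4 and -16.6. In the untreated groups replicate 3 lay at 17.2 in 4T1 and 17.3 in 4T1.2, and the other samples between -18.8 and 3.96. Samples of equal number were alike across groups, as 12 of 12 correlated best with a sample of their own number in deviations from the group means. No label gives a shared day for samples of 1 replicate number, and whether they share one was not tested.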
